A study of Saccharomyces cerevisiae S288C with 6 samples.

How the data were processed

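Gene expression was measured in 6 libraries of Saccharomyces cerevisiae S288C, 3 labelled wild type and 3 labelled homozygous ltv1 deletion. Per the labels' protocols, RNA was extracted with hot phenol, 3' tag libraries with inline molecular identifiers and sample indexes were sequenced as single-end reads of 84 to 90 cycles. Per the submitters' processing notes the tools were FastQC, Trim Galore, STAR, Salmon, DESeq2 1.34.0 and R 4.1.3, with genome build R64. How the molecular identifiers were used, the settings, and the strand used in counting are not given in the sources used here. Where genes overlap or have near-identical copies, the authors' counting could have split reads between them.

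The deposited table of 7126 rows holds a normalized signal per gene and library, and the authors' log2 fold change, its standard error, p-value and adjusted p-value. In each library's deposited signal, 100% of the values above 0 were whole multiples (within 0.01) of 1 step, the worth of 1 read, between 0.914 and 1.07, as gene counts divided by a size factor give. The whole reads recovered came to between 1002573 and 1248710 per library, fewer than the reads per sample that the labels state. A floor of 3 reads in 1 library is worth between 2.74 and 3.22 normalized counts. Intervals and floors cover counting error only. The highest gene, TDH3, took 5.66% of the reads of wild type 1 and 1.33% to 2.88% of those of the others. The mean level in the authors' deposited table was not the mean of the 6 libraries. In 94 rows it was above 0 where all 6 libraries were at 0, so the authors' fit held values not analysed here. Of the p-values that the authors deposited, 52.1% were exactly 1. Of 7126 identifiers, 6048 matched a locus tag of the reference annotation, whose build is R64 as in the submitters' notes. Coordinates are those of the annotated genes and 1-based.

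Groups were taken from the labels. The design had named edgeR's quasi-likelihood test for counts, and for values divided by size factors limma on log2(value + 1), with a mean of at least 5 over the 6 libraries. The table held the second kind, so limma 3.58.1 was used in R 4.3.3, with no trend and no robust option, Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are ltv1 deletion minus wild type on the log2(value + 1) scale, which understates the change of genes with low values. Count tests on the recovered reads (edgeR 4.0.16, DESeq2 1.42.0 and limma-voom) were added after seeing the data, and called 1166 genes with edgeR and its TMM factors. In total 30 gene lists were fixed before the data were examined, and 28 with at least 4 tested members were tested with limma's camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. With an estimated correlation 0 of the 28 lists were called. The fry test, which asks whether a list's genes moved on balance one way without comparing them with other genes, gave an adjusted p of 0.0251 for the assembly lists, the polymerase list, both stress lists, autophagy, the tricarboxylic acid cycle list and the sulfur list, and of 0.0412 for heat shock and the respiratory chain and 0.0363 for the marker genes. Of the 19 lists that camera called, the other 7 did not pass fry: 40S ribosomal proteins (0.262), 60S ribosomal proteins (0.204), proteasome (0.0533), mitochondrial ribosomal proteins (0.125), glycolysis (0.206), cell wall (0.159) and cell cycle (0.0809).

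Genes were named by a rule fixed before the data were examined. LTV1 came first. Then came the 10 largest log2 fold changes in each direction, LTV1 left out, among genes past the threshold with a mean of at least 10 in the higher group and no overlap between groups. For each list called, up to 4 members with the smallest adjusted p in its direction were taken, and up to 2 against it. For each other list up to 2 members past the threshold were taken, and then the genes next to LTV1. The rule gave 105 genes. The text gives the values of most of them.

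The procedure was tested on simulated data, 5 runs of 6770 genes drawn at the real means and depths of the comparison of ltv1 deletion and wild type. In each run 200 genes were changed, and the members of 1 list were shifted 1.5-fold. The real fit called 898 genes, and the share called depends on how many genes change, so the shares below need not carry over. Of genes changed 4-fold 89.1% were called in the right direction, of genes changed 2-fold 11.0%, and of genes changed 1.5-fold 0 of 335. Of unchanged genes 0.0629% were called. A shifted list was called in 5 of 5 runs, and 1 of 135 unshifted lists was. The simulated genes were drawn independently of each other, so these list rates do not carry over to lists of correlated genes. In the real libraries the estimated correlation reached 0.762, in the 60S assembly factors. The alternatives were other scalings, filters, pseudocounts, thresholds and tests, the replicate number as a block, and leaving out each library in turn. Leaving out wild type 3 and ltv1 deletion 1 together was added after seeing the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.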

Results

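Messenger RNA was measured in the budding yeast strain S288C, the laboratory strain behind the reference genome, in 3 libraries labelled wild type and 3 labelled homozygous ltv1 deletion, that is, with the LTV1 gene deleted on both copies. Ltv1 is an assembly factor of the small (40S) ribosomal subunit, and the comparison asks how expression differs without it. Cells were grown in rich medium at 30 °C to an optical density of 0.5 to 0.6. The libraries held tags from the 3' ends of polyadenylated RNA. Whole reads recovered from the deposited values came to 1248710, 1002573 and 1186640 for wild type 1, 2 and 3, and to 1077569, 1080176 and 1206279 for ltv1 deletion 1, 2 and 3. Between 6245 and 6332 genes had at least 1 read in a library. The labels do not say whether replicates were separate cultures, so the p-values below measure only the spread between these samples.

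LTV1 itself (YKL143W, chromosome XI, 176781 to 178172, build R64) did not follow the labels. Its normalized read count was 29.2, 191 and 8.77 in the libraries labelled wild type 1, 2 and 3. In those labelled ltv1 deletion 1, 2 and 3 it was 680, 3.22 and 6.40, from 647, 3 and 7 reads. The library labelled ltv1 deletion 1 thus held more LTV1 reads than any other library, and the one labelled wild type 3, with 9 reads, was close to the low libraries. The group means were 76.2 ± 99.6 (SD, n = 3) for wild type and 229.9 ± 389.9 (SD, n = 3) for the deletion, with an exact two-sided permutation p of 1 (smallest possible 0.1). The log2 fold change was -0.47 with a standard error of 1.92 (limma adjusted p = 0.886), and its sign turned with the settings. The extent of the deletion is not given in the sources used here, and a 3' tag outside the deleted part would check nothing. Every direction below therefore compares libraries by their labels, ltv1 deletion against wild type, and the LTV1 reads go against 1 of those labels or more. Of the neighbouring genes, RPC25 (YKL144C, chromosome XI, 175843 to 176481), a subunit of RNA polymerase III, was higher in the libraries labelled ltv1 deletion (log2 fold change 2.51, adjusted p = 0.0153). Its wild type values of 0.97, 5.21 and 1.95, from 8 reads in total, lay near the floor of 3 reads. MRP8 (YKL142W, chromosome XI, 178515 to 179174) had a log2 fold change of -0.70 that missed the threshold in limma (adjusted p = 0.0680) and passed it in edgeR on recovered reads (adjusted p = 0.0414).

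**Figure D1:**
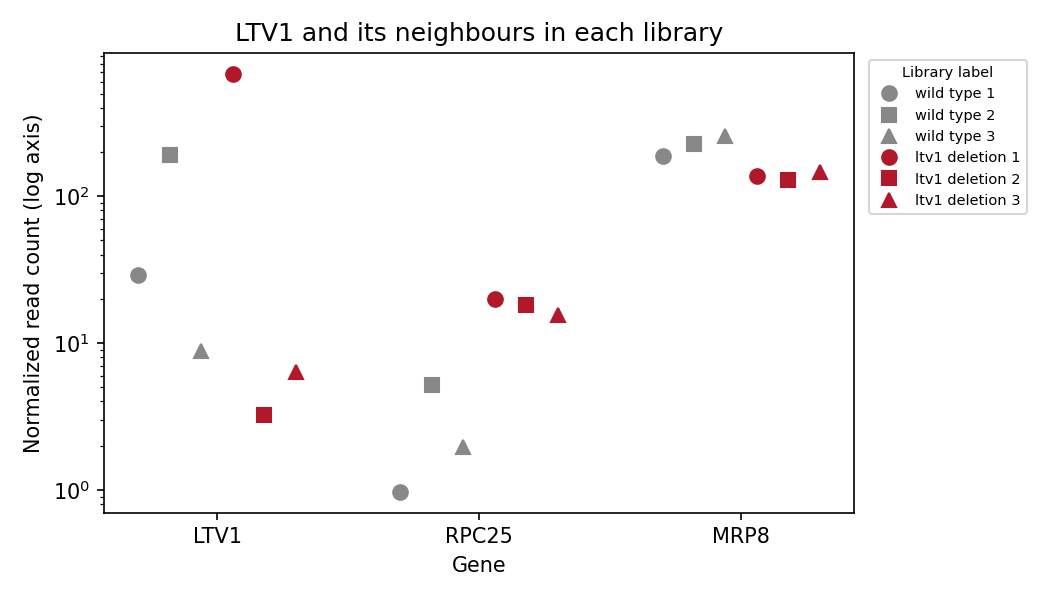
Normalized read count (log axis) of LTV1 and of the genes next to it, RPC25 and MRP8, with 1 point per library and the marker shape giving the replicate number. LTV1 reached 680 in the library labelled ltv1 deletion 1 and 8.77 in the one labelled wild type 3.

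Many genes for building ribosomes were higher, and many of stress defence lower, in the libraries labelled ltv1 deletion. Of 62 tested 60S assembly factors 58 rose, and of 52 members of the small-subunit processome, which starts 40S assembly, 46 rose. Of 54 general stress response genes 30 fell, and of 58 genes of oxidative stress defence 26 fell and 1 rose. The detoxification gene FLR1 was 20.6-fold lower and the 60S assembly gene YTM1 6.03-fold higher. All of these directions follow the labels, which LTV1 does not.

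Of 5663 genes tested with limma, 898 passed an adjusted p of 0.05, 503 higher and 395 lower in the libraries labelled ltv1 deletion. Among them 807 differed by over 2-fold and 228 by over 4-fold, on the log2(value + 1) scale. The 3 values of one label lay apart from the 3 of the other in 2357 genes (41.6%, where chance gives 10%). The number of calls rested on which libraries were used. It was 557 without wild type 3, 159 without ltv1 deletion 1, 202 without ltv1 deletion 2 and 37 without ltv1 deletion 3. Without wild type 1 the genes lower numbered 220 in place of 395. Without both wild type 3 and ltv1 deletion 1, whose LTV1 reads were out of place, 16 genes passed, 12 higher and 4 lower, and 1445 had an unadjusted p under 0.05. Of these 16 genes, 7 were among the 898. No gene among the 898 changed sign in any of these fits. They were picked for their difference in the same libraries, so a change of sign was unlikely from the start. The list counts below use all 6 libraries. At most 3 members of any list passed without ltv1 deletion 3, 7 without ltv1 deletion 1, 13 without ltv1 deletion 2 and 0 without both wild type 3 and ltv1 deletion 1. The first principal component held 59.1% of the variance and parted the 2 labels. The libraries labelled wild type 1, 2 and 3 scored -59.4, -15.5 and -27.9, and the deletion libraries 28.5 to 38.7. Wild type 1 lay furthest out. The second component held 13.9% and did not follow the labels. On it wild type 1, wild type 2 and ltv1 deletion 1 scored 3.34, 20.7 and 25.5. Wild type 3, ltv1 deletion 2 and ltv1 deletion 3 scored -18.5, -17.1 and -13.9.

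The 60S assembly factors had a median log2 fold change of 2.04 (58 of 62 rose, 60 adjusted over the list alone; limma's camera, adjusted p = 4.99e-26). With an estimated correlation between genes the list was not called (adjusted p = 0.370 with an estimated correlation). YTM1, DBP2, RLP24 and NUG1, factors of pre-60S assembly and export, had log2 fold changes of 2.59, 3.09, 2.64 and 2.07. NUG1 went from 465 ± 189.8 to 1858 ± 85.4 (SD, n = 3 each). The small-subunit processome had a median of 1.88 (46 of 52 rose, 50 adjusted over the list alone; camera adjusted p = 1.34e-20, and adjusted p = 0.370 with an estimated correlation). UTP15, UTP23, UTP18 and NOC4 stood at 1.63, 3.18, 1.98 and 1.96. The late 40S assembly and export factors, the group that works beside Ltv1, had a median of 1.45 (17 of 23 rose, 18 adjusted over the list alone; camera adjusted p = 1.12e-08, and adjusted p = 0.370 with an estimated correlation). SLX9, TSR4, FYV7 and ENP1, the last a known partner of Ltv1, had log2 fold changes of 2.40, 1.31, 2.28 and 2.44. Among RNA polymerase I and III genes 19 of 30 rose (22 higher and 1 lower adjusted over the list alone; median 1.41, camera adjusted p = 5.97e-09, and adjusted p = 0.370 with an estimated correlation), with RPC53 at 1.69, RRN3 at 1.68 and RPC82 at 1.40. Wild type 1 had the lowest mean of the 60S assembly list, -1.81 on the log2 scale relative to the mean of all 6 libraries, against -0.38 in wild type 2 and -0.80 in wild type 3. The deletion libraries stood at 0.90 to 1.09. The median of the 60S assembly factors ranged from 1.61 to 2.39 with 1 library left out. The calls of single genes did not last, as of the 60S assembly factors 46 passed without wild type 3, 7 without ltv1 deletion 1, 12 without ltv1 deletion 2 and 2 without ltv1 deletion 3. Without wild type 3 the processome, late 40S and polymerase genes that rose numbered 28, 11 and 12. Without both wild type 3 and ltv1 deletion 1, limma called 0 of the 62, of which 59 were higher at an unadjusted p under 0.05, with a median of 2.10.

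**Figure D2:**
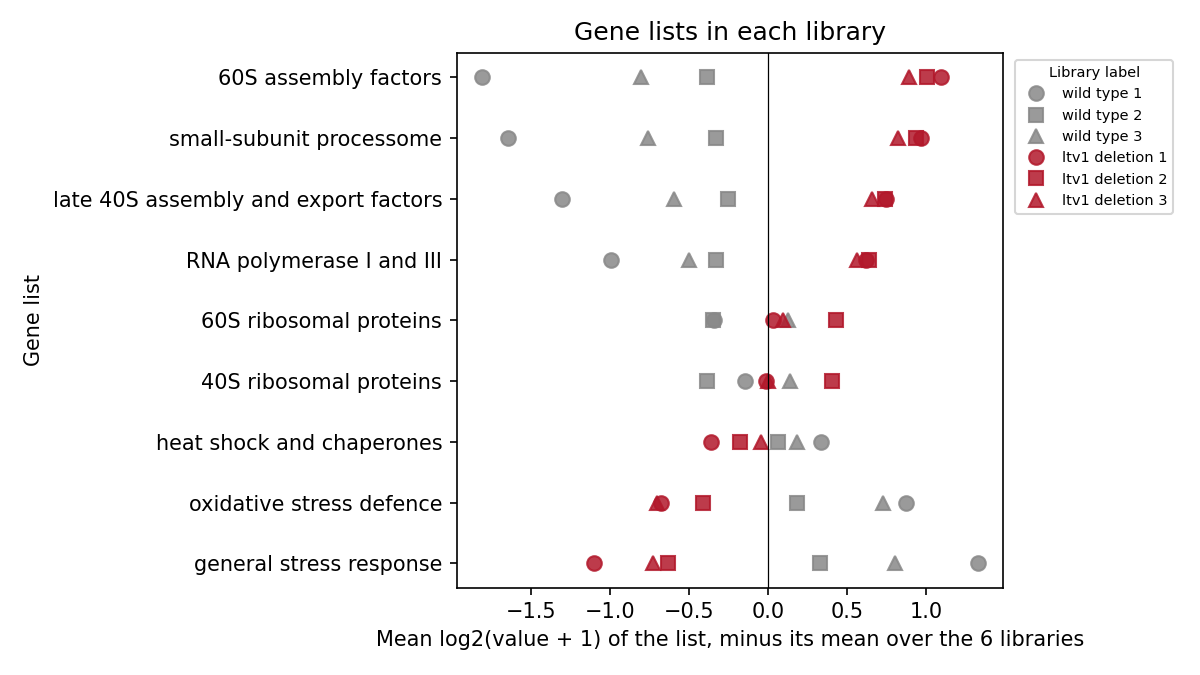
Mean of log2(value + 1) over the tested members of 9 gene lists in each library, minus the mean over the 6 libraries, with 1 point per library and the marker shape giving the replicate number. For the 60S assembly factors the libraries labelled wild type lay between -1.81 and -0.38 and those labelled ltv1 deletion between 0.90 and 1.09.

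Of 81 genes for 60S ribosomal proteins 6 rose and 1 fell (5 and 1 adjusted over the list alone; median log2 fold change 0.33, camera adjusted p = 0.00239, and adjusted p = 0.508 with an estimated correlation). Of 57 genes for 40S ribosomal proteins 2 rose (1 adjusted over the list alone; median 0.23, camera adjusted p = 0.0343, and adjusted p = 0.577 with an estimated correlation). The members that passed included RPL18B at 1.99, RPL7B at 1.43, RPL15A at 1.45, RPL22B at 1.56 and RPS9A at 2.05, with RPS19A at 1.09 and RPL9B going down at -1.16. Most of these genes have a near-identical paralog, so the share of reads given to each copy is uncertain. Without ltv1 deletion 2 the medians were 0.17 (60S) and 0.08 (40S), and the 40S median was 0.10 without wild type 2 and 0.42 without wild type 3. The call of RPL9B ended without wild type 1 and without wild type 3. Both lists lost their camera call without wild type 2 or without ltv1 deletion 2, and the 40S list also with quantile normalization and with a mean value of at least 50.

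Of 58 genes of oxidative stress defence 26 fell and 1 rose in the libraries labelled ltv1 deletion (37 and 3 adjusted over the list alone; median log2 fold change -1.16). Limma's camera gave an adjusted p of 3.21e-09, and adjusted p = 0.370 with an estimated correlation. The transporter genes FLR1 and ATR1, which export drugs from the cell, had log2 fold changes of -4.37 and -2.78. FLR1 (YBR008C, chromosome II, 252563 to 254209) went from 1531 ± 891 to 73.9 ± 49.7 (SD, n = 3 each; standard error of the log2 fold change 0.57, adjusted p = 0.0126). The glutathione transferase gene GTT2 (YLL060C, chromosome XII, 21138 to 21839) was at -4.15 and went from 92.8 ± 20.8 to 4.88 ± 3.44 (SD, n = 3 each). AAD6, of the aryl-alcohol dehydrogenase family, was at -3.80. TAL1, the transaldolase of the pentose phosphate pathway, went the other way at 1.68. The general stress response list had a median of -1.49 (30 of 54 fell, 41 adjusted over the list alone; camera adjusted p = 5.22e-17, and adjusted p = 0.370 with an estimated correlation). Its members SSE2, a chaperone, APE1, a vacuolar aminopeptidase, GPH1, glycogen phosphorylase, and DCS2 stood at -2.17, -3.55, -2.79 and -2.35. Wild type 1 had the highest mean of the general stress list at 1.33 over the mean of all libraries, with wild type 2 at 0.33 and wild type 3 at 0.80. Without wild type 1, without wild type 3, and without ltv1 deletion 1, 2 and 3, the general stress genes that fell numbered 19, 19, 7, 13 and 2, and the oxidative stress genes 15, 12, 6, 10 and 3. Without both wild type 3 and ltv1 deletion 1 limma called 0 members of either list, with 34 of the general stress genes and 30 of the oxidative stress genes lower at an unadjusted p under 0.05.

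In other lists of protein quality control a minority of genes passed the threshold. Of 39 heat shock and chaperone genes 8 fell and 1 rose (12 and 1 adjusted over the list alone; median log2 fold change -0.24, camera adjusted p = 0.0447, and adjusted p = 0.504 with an estimated correlation). SSA4 at -2.05, HSP82 at -1.45 and CPR6 at -1.20 fell, and CNS1 rose at 1.45. The heat shock genes that fell numbered 4 without wild type 1 and 3 without wild type 3, and the autophagy genes 4 and 3. The call of CNS1 ended without wild type 3, where 1 proteasome gene fell, and that of YLR312C without wild type 1, 2 or 3. The median of the heat shock list was -0.36 without wild type 2 and -0.15 without ltv1 deletion 1. Its call ended without wild type 3, without ltv1 deletion 1 and without ltv1 deletion 2. Of 43 proteasome genes 2 fell, RPT1 at -1.36 and UMP1 at -1.50 (0 adjusted over the list alone, where limma gave 12 at an unadjusted p under 0.05 and edgeR called 5 over all genes; list median -0.43, camera adjusted p = 0.000398, and adjusted p = 0.504 with an estimated correlation). Of 42 autophagy genes 7 fell and 1 rose, the same numbers adjusted over the list alone (median -0.52, camera adjusted p = 5.86e-05, and adjusted p = 0.370 with an estimated correlation). APE1, ATG33 at -2.20, PEP4 at -1.47 and ATG34 at -2.12 fell, and YLR312C rose at 0.82.

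In 5 lists of energy and sulfur metabolism that camera called, between 2 and 8 genes fell. Of 45 genes of the respiratory chain and ATP synthase 8 fell (8 lower and 1 higher adjusted over the list alone; median log2 fold change -0.52, camera adjusted p = 0.000257, and adjusted p = 0.370 with an estimated correlation), among them STF1, COX12, COX8 and COX6 at -1.91, -2.11, -2.04 and -1.92. Of 30 genes of the tricarboxylic acid and glyoxylate cycles 4 fell, LSC2, CIT2, MDH1 and DAL7 (4 adjusted over the list alone; median -0.57, camera adjusted p = 0.000533, and adjusted p = 0.370 with an estimated correlation). Of 27 genes of glycolysis and fermentation 4 fell (5 adjusted over the list alone; median -0.66, camera adjusted p = 0.0123, and adjusted p = 0.509 with an estimated correlation). They were PYK2 at -1.59, TDH1 at -3.21, ALD4 at -1.81 and HXK1 at -2.29. TDH1 had 8182 in wild type 1 against 1336 and 1063 in wild type 2 and 3. The mean of the glycolysis list, relative to all 6 libraries, was 1.12 in wild type 1, 0.07 and -0.06 in wild type 2 and 3, and -0.41 to -0.34 in the deletion libraries. Without wild type 1 its median was -0.44, with 3 genes lower and 1 higher. Of 69 genes for mitochondrial ribosomal proteins 2 fell, MRP49 at -1.85 and MRPL35 at -1.15 (1 adjusted over the list alone; median -0.25, camera adjusted p = 0.00803, and adjusted p = 0.504 with an estimated correlation). That call ended without wild type 3, without ltv1 deletion 3 and with a mean value of at least 50. Of 31 genes of sulfur assimilation and methionine synthesis 6 fell (6 adjusted over the list alone; median -0.49, camera adjusted p = 0.00410, and adjusted p = 0.370 with an estimated correlation). The methionine permease genes MUP3 and MUP1 stood at -2.51 and -1.46, and the synthesis genes MET6 and MET16 at -2.00 and -2.06. MUP3 stood at 362 ± 2.89 against 63.1 ± 4.82 (SD, n = 3 each). Without wild type 1 and without wild type 3 the genes that fell numbered 5 and 4 in the respiratory list, 2 and 2 in the cycles and 4 and 3 in the sulfur list, whose median without wild type 3 was -0.32. Of the mitochondrial ribosomal protein genes 1, 5 and 1 fell without wild type 1, 2 and 3, and their median was -0.16 without wild type 3 and -0.15 without ltv1 deletion 3.

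Of 40 cell wall genes 5 rose (5 adjusted over the list alone; median log2 fold change 0.22, camera adjusted p = 0.0291, and adjusted p = 0.508 with an estimated correlation), including YPS3 at 1.90, the cell wall kinase gene SLT2 at 1.41, UTR2 at 1.67 and the chitin synthase gene CHS1 at 1.27. Of 47 cell cycle and histone genes 3 rose, HTA1 at 1.57, PCL1 at 1.29 and DSE4 at 0.89 (1 adjusted over the list alone; median 0.34, camera adjusted p = 0.0291, and adjusted p = 0.504 with an estimated correlation). Both calls ended without wild type 3, without ltv1 deletion 1 and with a mean value of at least 50, and the cell cycle call also without wild type 1, where its median was 0.22. The cell wall median was 0.13 without ltv1 deletion 1. Without wild type 3 the genes that rose numbered 2 in the cell wall list and 1 in the cell cycle list, and without wild type 1 the cell cycle list had 1. Of 11 marker genes used in yeast genetics 4 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.84, camera adjusted p = 0.0140, and adjusted p = 0.458 with an estimated correlation). MET17, ADE8, ADE2 and ADE1 stood at -2.75, -1.62, -1.71 and -2.17, and URA1 at 2.29. The marker genes that fell numbered 2 without wild type 1, and the call of URA1 ended without wild type 1 and without wild type 3. Each of these genes had reads in all 6 libraries.

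The lists that camera did not call still held single genes past the threshold. Of 30 genes of the endoplasmic reticulum unfolded protein response 2 fell, OPI3 at -1.93 and ERO1 at -1.14 (2 adjusted over the list alone; camera adjusted p = 0.219). Of 60 amino acid synthesis genes 2 rose and 6 fell, with ILV5 at 2.00 and BAT2 at -1.44 (2 and 6 adjusted over the list alone; camera adjusted p = 0.252). Of 32 iron regulon genes 5 rose and 1 fell, with the high-affinity iron uptake genes FET3 at 2.39 and FTR1 at 1.61 (6 and 1 adjusted over the list alone; camera adjusted p = 0.252). Of 26 genes of hexose transport and glucose repression ADR1 at -1.74 and REG2 at -1.49 fell (2 adjusted over the list alone; camera adjusted p = 0.268). Of 30 DNA damage genes 1 rose and 4 fell, with MAG1 at -1.48 and PHR1 at -1.16 (1 and 5 adjusted over the list alone; camera adjusted p = 0.327). Of 27 ergosterol genes ERG1 rose, at 1.33 (0 adjusted over the list alone, where limma gave 5 higher at an unadjusted p under 0.05 and edgeR called 4 over all genes; camera adjusted p = 0.252). Of 22 phosphate genes PHO90 rose, at 1.87 (1 adjusted over the list alone; camera adjusted p = 0.450). Of 18 meiosis genes SPS100 fell, at -2.16 (0 adjusted over the list alone, with 3 lower at an unadjusted p under 0.05 in limma and 1 called by edgeR over all genes; camera adjusted p = 0.723). Of 8 haploid-specific genes NEJ1 rose, at 2.22 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.854). The DNA damage genes that fell numbered 1 without wild type 1 and 1 without wild type 3, as did the amino acid genes that rose. The iron genes that rose numbered 3 without wild type 3, where the call of ERG1 also ended, while without wild type 2 the ergosterol genes that rose numbered 3 and the meiosis genes that fell 2. NEJ1 had 7 reads over the wild type libraries, near the floor, and 36 over the deletion libraries, and edgeR's filter left it out. The call of NEJ1 ended without wild type 1. Of the a-cell and alpha-cell genes, 2 and 1 were abundant enough to test, and limma called 0 of them, with 0 at an unadjusted p under 0.05 and 0 called by edgeR.

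The gene furthest down in the libraries labelled ltv1 deletion was YKL071W (chromosome XI, 305114 to 305884), with 219 ± 255 against 2.03 ± 1.10 (SD, n = 3 each; log2 fold change -5.59, standard error 0.75, limma adjusted p = 0.0126). OYE3, an NADPH dehydrogenase, followed at -5.35, then IMD2, of the IMP dehydrogenase family of guanine nucleotide synthesis, at -4.94. AAD16, FLR1, YHR219W, GTT2, YML131W, AAD6 and YNR034W-A lay between -4.60 and -3.69. In ltv1 deletion 1, 2 and 3 OYE3 stood at 0, 17.2 and 1.83 (standard error 1.05) and YHR219W at 0, 12.9 and 0. Their places in this order are therefore uncertain. Reads of IMD2, AAD16, AAD6 and the subtelomeric YHR219W can be shared with near-identical genes, so these values are uncertain. The genes furthest up included DHR2, HCA4 and FAF1, which act in the small-subunit processome, at 3.42, 3.42 and 3.40, the late 60S factor gene SDA1 at 3.18, JJJ3 at 3.77 and SET6 at 3.38. JJJ3 had 6 reads over the wild type libraries, near the floor. HCA4 (YJL033W, chromosome X, 383837 to 386149) went from 59.4 ± 43.6 to 521 ± 60.6 (SD, n = 3 each; standard error 0.56, adjusted p = 0.0153). The leucine tRNA gene tL(UAA)B1 had no read in the wild type libraries. Its reads were at least 22.6-fold higher in the deletion libraries, against a floor of 3 reads over the group. YMR230W-A had 1 read in the wild type libraries, and the ratio was 63.8 (exact 95% counting interval 11.0 to 2561). FEX1 at 4.27 and the proline tRNA gene SUF10 at 3.79 completed the set. The tRNA genes and FEX1 have near-identical copies, and their values are uncertain for that reason. The libraries held tags of polyadenylated RNA, so reads at tRNA genes need not follow the level of the tRNAs. For tL(UAA)B1, SUF10 and FEX1 the authors' deposited table gives log2 fold changes of 0.33, 0.23 and 0.96, each marked as insignificant in a test whose settings are not given. SUF10 had 4 reads over the wild type libraries.

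**Figure D3:**
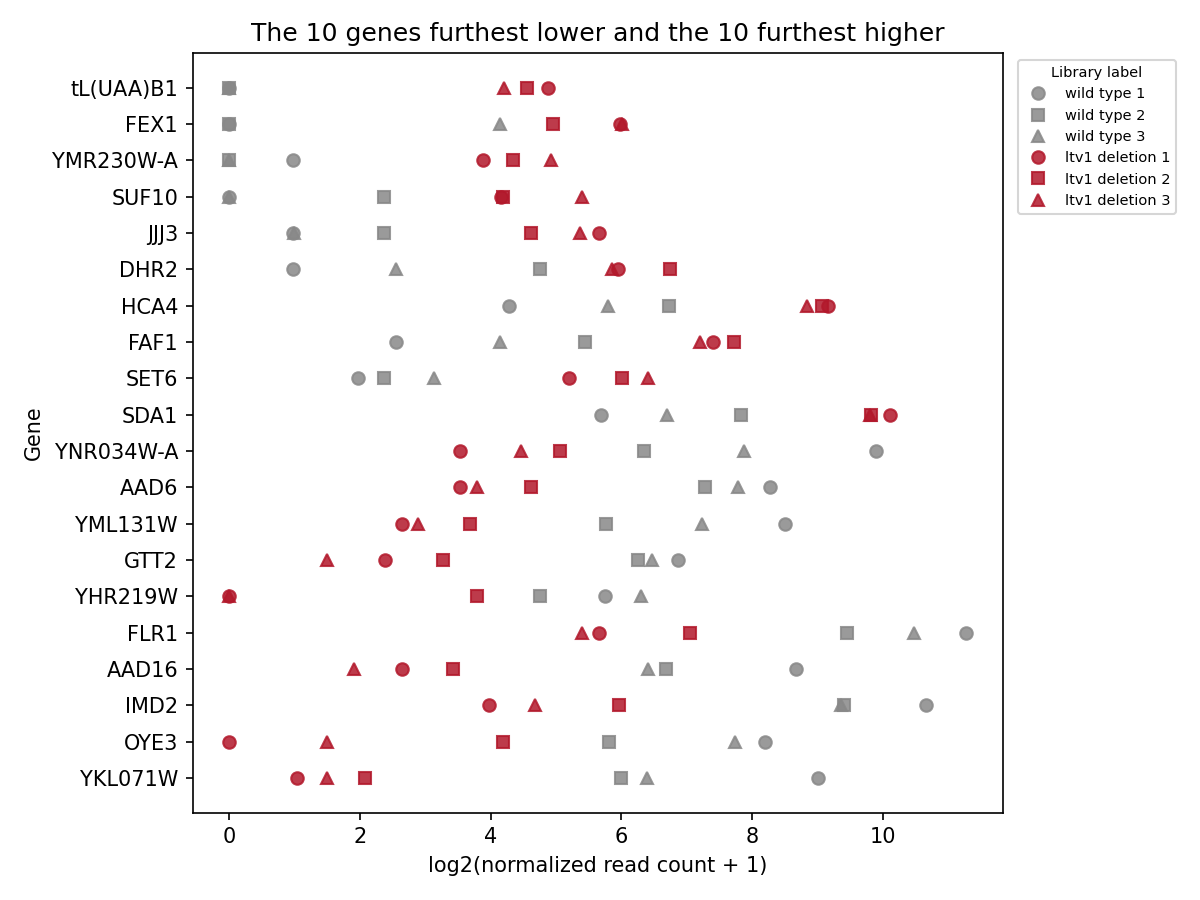
log2(normalized read count + 1) of the 10 genes furthest lower and the 10 furthest higher in the libraries labelled ltv1 deletion, with 1 point per library and the marker shape giving the replicate number. In each gene the 3 points of one label lie apart from the 3 of the other, which was a condition for naming the gene, and YKL071W lay furthest down at -5.59.

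The authors' deposited table marks 86 genes as significant, 34 higher and 52 lower in the deletion. All 86 were among the 898 genes called here, with the same sign. The 86 are a far smaller set, with a smallest absolute log2 fold change of 1.52, so finding them among the 898 says little. The settings of the authors' test are not given in the sources used here. It may have asked for a minimum fold change, where the 898 were tested against no change, so the 2 numbers may not be comparable. Against a 1.5-fold change limma called 51 genes here. The 2 sets of calls are not independent, since both use these 6 libraries, and the authors' deposited table also rests on values not analysed here. Across the 5663 genes tested here, which are not independent replicates, the log2 fold changes of the authors' deposited table correlated with those computed here at r = 0.817. The authors' deposited table marks LTV1 as insignificant, under the same unknown settings.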

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

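The tests of genes on recovered reads and the fit without wild type 3 and ltv1 deletion 1 were chosen after seeing the data, and the other alternatives, with limma-voom weights for the gene lists among them, before. The number of genes changed (898) stayed within 1.5 times with quantile normalization, median centring, both filters, both pseudocounts, a mean-variance trend, and edgeR, DESeq2 and limma-voom on recovered reads, from 695 to 1166. It was 51 against a 1.5-fold change, 24 at an adjusted p under 0.01, and 16 (12 higher, 4 lower) without wild type 3 and ltv1 deletion 1, a fit with fewer libraries. With 1 library left out it ranged from 37 to 981, the genes higher from 20 to 533 and the genes lower from 17 to 448. Fewer samples lower the power of these fits, and why the deletion libraries weighed most was not tested. None of the 898 calls changed sign in any alternative that tested it, which was likely from the start for genes picked in the same libraries. With the replicate number as a block it was 430 (279 higher, 151 lower), and 18 of the 19 lists were called, all but heat shock. Same-numbered libraries had deviations correlated across genes at -0.105, -0.198 and 0.072, so the numbers were not taken to pair the samples. Not every library correlated best with its own number.

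The number of gene lists changed (19) was between 15 and 19 in every alternative that kept the preset correlation, and 0 with an estimated correlation, where limma's camera without adjustment gave 2 lists under 0.05. LTV1 was the only named gene whose sign turned. Its log2 fold change was -0.47 in limma on all libraries, -2.78 without ltv1 deletion 1, -1.46 without wild type 3 and -3.77 without both (limma adjusted p = 0.0990). It was 0.69 without wild type 2, 0.89 without ltv1 deletion 2 and 0.48 without ltv1 deletion 3. It was 1.59, 1.60 and 1.53 in edgeR with TMM, RLE and library totals, and 1.59 in DESeq2. These count tests model mean counts, and the mean was higher in the deletion, 229.9 against 76.2, while limma averages log2 values. Why LTV1 differed so between libraries of 1 label stays open. Of 105 named genes, 99 lost their call without wild type 3 and ltv1 deletion 1 together, 89 without ltv1 deletion 3, 66 without ltv1 deletion 1, 51 without ltv1 deletion 2, 26 without wild type 3, 23 without wild type 1, 7 without wild type 2, 30 with the block and 11 without a filter on low values. Depth limits the genes near the floor of 3 reads. In simulated libraries of this depth, with 200 genes changed per run, most 2-fold changes were missed. That share need not carry over to the real libraries, where 898 genes were called.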

Other observations

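The fit without wild type 1 was planned before the data were examined, but its use as a test of the pattern below was chosen after the results were seen. So were the correlation over list members, the tests of exchanged strains or libraries and of carried-over reads, and the reading of the other splits. The genes below were picked after their values were seen. The library labelled wild type 1 held 1845 normalized reads of the copper metallothionein gene CUP1-1, where the others held 95.7 to 226, although CUP1-1 has an identical copy and its level is uncertain. It also held 182 of IZH4, against 1.95 to 13.7 in the others, and 68676 of TDH3, against 14657 to 33326.

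In the libraries labelled ltv1 deletion 58 of 62 60S assembly factors and 46 of 52 processome genes rose, and 30 of 54 general stress and 26 of 58 oxidative stress genes fell (1 of the latter rose), though each of these 4 lists had an adjusted p of 0.370 with an estimated correlation, and the 4 medians did not rest on wild type 1 alone. Without that library each list kept at least 76.4% of its median, over the members tested in both fits. A state of the cells that also varies between cultures of 1 label may contribute. The difference between 2 wild type libraries was correlated across genes with the difference between the deletion libraries and the left-out wild type library. Over all genes the absolute r was 0.162, 0.343 and 0.463, where over 0.3 for each had been set beforehand and was missed in 1 of the 3. In a test added after that, it was 0.640 to 0.838 over the members of the 4 lists. Those lists were taken because the assembly lists rose and the stress lists fell between the labels. An offset between the assembly and the stress lists alone can give such an r, so this second test cannot decide. Such a state and the genotype cannot be told apart over all genes, since the labels record no growth measure per library, and the genotype itself was untested given the LTV1 reads.

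A split of wild type 1, wild type 2 and ltv1 deletion 1 from the other 3 libraries left no overlap in 521 of 5663 genes, where another split that does not follow the labels gave 652, but a gap of over 2-fold in 12 genes, LTV1 among them, and of over 4-fold in 7 others than LTV1, where the other splits that do not follow the labels gave at most 7 and 4. PRM2 stood at 17.5, 20.8 and 7.36 in those 3, against 702, 866 and 487 in wild type 3 and ltv1 deletion 2 and 3, NUP85, MTM1, STU1 and TFB2 went the same way, and YLR256W-A and YBL112C had reads only in the first 3, though both lie in repeated sequence and are uncertain. The second principal component, over all tested genes, also parted the libraries by this split, though wild type 1, at 3.34, lay nearest the other side. An exchange of 2 whole libraries, with genotype behind the transcriptome-wide difference, is argued against because wild type 3 and ltv1 deletion 1 correlated more with their own label's libraries, by at least 0.0477 in mean r. Carry-over of LTV1 reads from the 3 wild type libraries is argued against because ltv1 deletion 1 held 3.57 times the value of wild type 2 (exact 95% counting interval 3.02 to 4.23). An exchange of the strains behind 2 cultures, with another condition shared within a label behind the transcriptome-wide difference, may account for both observations and stays open, since the 7 genes prompted it and cannot test it, and the labels give no such condition. By itself it would leave unexplained the wide range of LTV1, at 29.2, 191 and 680 in wild type 1, wild type 2 and ltv1 deletion 1.

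The 6 libraries can be split 3 and 3 in 10 ways, too few for a share under 0.05. The split by label gave 898 genes changed, as many as in 1 of the 10 splits, its own, and the highest other split gave 7. For gene lists the split by label gave 19, again 1 of the 10, and the highest other split gave 16, so camera with its preset correlation called many lists in splits that do not follow the labels. Each of the other splits had libraries of both labels on each side. Any difference between the labels thus widened their spread, which lowers gene calls, and stayed in part in their contrast, which can shift lists. The other splits therefore do not show what would be called without a label difference.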
